A study of Arabidopsis thaliana with 4 samples.

How the data were processed

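Gene expression was measured in whole seedlings of Arabidopsis thaliana Col-0 on 4 one-colour Agilent 4x44K Arabidopsis arrays, which lay on 1 slide at positions 1 to 4 and were read in 1 scan. Per the labels' protocols, seedlings were grown untreated on agar medium at 22 °C with 8 h of light and 16 h of darkness, sampled 14 days after germination, and 1 µg of total RNA was labelled with Cy3. The labels name 3 groups, WT (1 array), C3H17_OX (2 arrays) and atc3h17-1 (1 array), and the submitters' design text compares the 2 C3H17_OX samples with WT. With 1 slide and 1 scan there was no batch to test.

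The spot intensities were made with Agilent Feature Extraction 11.0.1.1, per the file headers, which subtracted the background with spatial detrending and detrended each array multiplicatively without normalization between arrays. The deposited processed signal is thus a linear intensity, and the deposited median spot and local background signals are raw pixel intensities. The files also hold 0 or 1 marks per spot for signal well above background, saturation and outliers, set by the same software per the file headers. The authors' series value table held linear intensities that matched the processed signal rounded to 3 significant digits, with column medians of 616, 620, 611 and 580 for WT, C3H17_OX arrays 1 and 2 and atc3h17-1. It was neither scaled between arrays nor centred. In it, 49, 43, 45 and 46 probes differed from the scanner value of 1 spot by more than 0.01 on the log2 scale, by up to 0.86, 4.61, 3.08 and 3.40. The comparison included the 50 probes spotted 5 times each, whose series value was set against 1 of their spots. Whether these were the probes that differed was not checked.

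Each array held 43803 non-control spots of 43603 distinct probes. The 75th percentile of the signal was 3487, 3407, 3383 and 3273, and 72.0%, 74.5%, 73.6% and 72.8% of the spots were well above background, in the order given above. No spot was saturated. The number of arrays limits the precision. Repeated spots of 17 probes had an SD of 0.175 on the log2 scale on the WT array, against 0.0525, 0.0454 and 0.0548 on the others. The WT array also had an uneven surface, with a local trend of -0.33 to 0.32 (2.5th to 97.5th percentile).

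The log2 of the processed signal minus each array's 75th percentile was used. Control spots and outlier spots were left out, which removed 70 probes, and repeated spots were averaged. A probe was kept if it was well above background on every array of at least 1 group, which left 32971 probes. Of the 43603 probes, 34348 (78.77%) were matched to 1 locus through the TAIR10.1 reference table by transcript accession, and 9255 were not. Only 35595 probes carried a RefSeq transcript accession, and no match by locus name was tried, so an unmatched probe may still belong to a known locus. The array annotation follows TAIR10 per the file headers, so the table served only for this matching, for names and for the order of neighbouring genes. No coordinates are given. A gene's value was the mean of the log2 values of its kept probes, for 20462 genes, of which 14404 had 1 probe. The locus AT2G02160 was taken as C3H17 from general knowledge, since the table pairs no such symbol with it.

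Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of 3 groups with 1 residual degree of freedom and 1.33 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 2-fold. Beside it, genes were counted that differed at least 2-fold from WT on both C3H17_OX arrays. The atc3h17-1 array was compared with WT by size alone. Where a probe or gene was well above background in only 1 of 2 groups, the fold is given as a bound, "at least N-fold". It sets the brighter group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. With an estimated correlation, camera draws on the 1 residual degree of freedom, so hardly any list could pass whatever its correlation. For atc3h17-1, the list median was placed among those of 10000 random lists of the same size matched on mean expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

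The groups, tests, thresholds, 20 gene lists, most other settings and the rule for named genes were fixed before the data were examined. The rule names C3H17; the 12 highest and 12 lowest genes of C3H17_OX against WT that passed limma and were at least 2-fold on both arrays, ranked by the smaller array difference; the 8 highest and 8 lowest of atc3h17-1 against WT; up to 4 members per list with the largest difference, for each line; and up to 5 genes per direction that moved oppositely in both lines. The lists cover promoters and repressors of flowering, floral organ identity, seed storage, seed regulators, abscisic acid and dehydration, photosynthesis, the clock, salicylate immunity, jasmonate and ethylene defence, flavonoids, the cell cycle, cell wall expansion, root markers, heat shock, senescence and starvation, auxin response, gibberellin, glucosinolates and reference genes.

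The other settings fixed beforehand were normexp background correction with an offset of 50, quantile normalization, median scaling, the series value table, no filter, a filter on all 4 arrays, the brightest probe per gene, probes in place of genes, an intensity trend in eBayes, other samples in the fit, other thresholds, leaving out either C3H17_OX array, and other list tests. Normexp ran on the median spot signal, because the mean spot signal planned for it was not among the columns used here. Settings chosen after seeing the data were removal of a position trend (the median difference from the other arrays over the 100 nearest spots), other baseline arrays, the mean of both C3H17_OX arrays as 1 sample, and a requirement that every probe of a gene move.

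The procedure was tested on simulated data for the comparison of C3H17_OX with WT, with 20462 genes and noise set from the repeated spots. limma recovered 2% of the genes simulated with a 1.5-fold change, 94% at 2.5-fold and 100% at 4-fold and 8-fold, and called 0 of 20262 unchanged genes. Without the fold threshold, 9073 unchanged genes passed the adjusted p, and with equal noise on all arrays 0 did. That noise came from 17 probes, so unchanged groups were also simulated with the differences between the C3H17_OX arrays, resampled within 20 bins of intensity, once as they were and once widened on the WT array by the ratio of repeated-spot SDs (3.57). Widening dim genes by a ratio from those 17 probes is an assumption. The SDs behind that ratio also hold the uneven WT surface. Without the position trend they were 0.106 on WT and 0.0668 and 0.0400 on the C3H17_OX arrays, a smaller ratio that was not simulated. With 1 list shifted, 1 list was called. The removed surface trend correlated at 0.995 with a simulated one.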

Results

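Transcript levels were compared among whole seedlings of 3 Arabidopsis genotypes 14 days after germination in short days. C3H17_OX plants overexpress C3H17, a gene for a CCCH-type zinc finger protein, and atc3h17-1 carries a mutant allele of the same gene by its name in the labels. WT and atc3h17-1 were measured on 1 array each and C3H17_OX on 2. The 2 C3H17_OX arrays differed by a median of 0.0322 on the log2 scale, less than the spot noise of 0.0565 and 0.0428 between repeated spots on each of them. Their difference did not carry over between separate probes of a gene (r = -0.04 over 4190 genes, against 0.60 to 0.78 for pairs of different genotypes). They were therefore counted as 1 sample, so that each genotype was represented by 1 sample, and no p-value below measures the spread between plants. The limma p-values rest on the repeatability of the C3H17_OX array pair, carried over to a WT array whose repeated spots varied more. The camera p-values at the preset correlation set the genes of a list against all other genes. Genes are not independent replicates in any of the correlations across genes given here.

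C3H17 (AT2G02160) was the first gene examined, as a check of the labels. In C3H17_OX, 1 of its 3 probes (A_84_P803253) was 4.57-fold and another (A_84_P847169) 5.60-fold higher than in WT, while the third, A_84_P221496, was at 0.981-fold. In atc3h17-1, A_84_P803253 and A_84_P221496 were not well above background, at least 42.7-fold and at least 502-fold below WT, and A_84_P847169 was at 1.41-fold of WT. The gene's mean over its probes rose by 1.55 ± 0.02 (SE) in C3H17_OX with a limma adjusted p of 0.00549, and no mean is given for atc3h17-1, where 2 of the 3 probes were not well above background. The probes disagreed in both lines, and with the brightest probe alone the C3H17_OX difference was -0.03 (limma adjusted p = 0.541). With probes well above background on all 4 arrays, which left A_84_P847169 alone, the C3H17_OX difference was 2.49 and the atc3h17-1 difference 0.50.

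**Figure D1:**
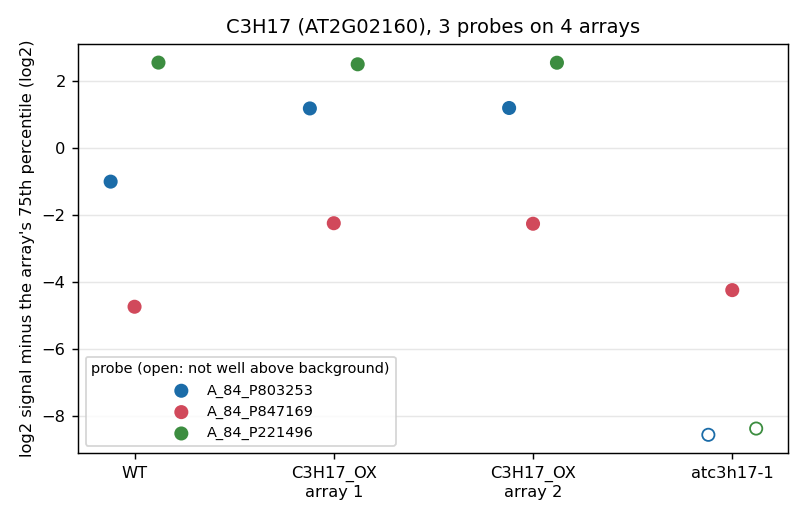
The log2 signal of the 3 C3H17 probes relative to each array's 75th percentile is plotted for the 4 arrays, with open points where a probe was not well above background. A_84_P803253 and A_84_P847169 lie higher on both C3H17_OX arrays than on WT, A_84_P221496 lies at 2.54 on WT and at 2.49 and 2.54 on the C3H17_OX arrays, and atc3h17-1 has only A_84_P847169 above background.

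The comparison of C3H17_OX with WT asked which genes respond to a higher level of C3H17. The genes furthest above WT included a pair of 12S seed storage proteins, CRA1 (at least 25.1-fold) and CRC (at least 12.2-fold), which had not been well above background in WT. Beside them stood PNP-A, a natriuretic peptide-like gene (63.5-fold), ELI3-2, an elicitor-activated alcohol dehydrogenase family gene (at least 51.4-fold), the tau-class glutathione S-transferases GSTU11 (51.7-fold) and GSTU3 (at least 9.10-fold), the pathogen and circadian controlled gene PCC1 (50.2-fold) and the lipid transfer protein gene LTP4 (at least 44.4-fold). AT1G09500 (at least 54.0-fold), MRD1 (36.5-fold), the Nudix hydrolase gene NUDT24 (at least 16.2-fold) and AT5G15560 (at least 7.60-fold) completed the 12 highest.

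At the other end, AT3G55920 was at least 145-fold, AT2G43280 at least 47.5-fold and AT3G05170 at least 28.2-fold lower in C3H17_OX than in WT, and these 3 were well above background in atc3h17-1, at -0.11, 0.61 and 0.20 relative to WT. The other 9 of the 12 lowest, AT4G30540 (at least 16.9-fold), AT5G20440 (at least 10.9-fold), AT1G13510, AT1G26890, AT3G14160, AT1G52390, ARI11, AT1G36230 and AT5G41890 (at least 5.11-fold, the smallest bound), had 1 probe each and were well above background on the WT array alone. Probes with a 4-fold excess on a single array and no detection elsewhere numbered 85 on WT, 135 and 94 on the C3H17_OX arrays and 123 on atc3h17-1. The C3H17_OX arrays, counted as 1 sample, thus held as many such spots as the others. For the 9 genes detected on the WT array alone, 1 bright WT spot therefore cannot be told apart from a lower level in C3H17_OX. All 24 genes passed limma with adjusted p-values between 0.00549 and 0.00597 and SEs between 0.02 and 0.20. Both rest on the spread of the C3H17_OX array pair, so neither holds the error of a WT spot.

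Across the array, 1462 of 20462 genes were at least 2-fold different from WT on both C3H17_OX arrays, 894 higher and 568 lower. limma called 1488 genes (906 higher, 582 lower), and 1391 met both criteria. The array pair of C3H17_OX differed from each other at least 2-fold in 238 genes. Unchanged groups simulated with noise resampled from that array pair gave 115 genes at least 2-fold from WT on both arrays and 0 limma calls. This noise was also widened 3.57 times on the WT array, the ratio of its repeated-spot SD to theirs. It then gave 620 genes by size and 378 limma calls. With that widening the covariance of both lines' differences from WT was 0.395, above the observed 0.325, so the widening probably overstates the noise. A share of the calls may still be noise of the WT array. With normexp background correction the higher share grew, with 859 higher and 286 lower by size and 913 and 302 by limma. The count by size was 940 when every probe had to be well above background on all 4 arrays. By size, 252 of the 1462 genes had several probes, against 6058 of all 20462, so genes with 1 probe passed more often. Of these 252, 144 had every probe past 2-fold and 240 had all probes in 1 direction. By adjusted p alone limma passed 13586 genes, and in the simulation 9073 of 20262 unchanged genes did so as well.

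Of 14 measured genes for seed storage proteins, oil bodies and late seed development, 10 rose and 1 fell, with a median of 2.26 on the log2 scale, or 1.23 with the 9 members not well above background in 1 group at their bound (camera adjusted p = 2.29e-04; adjusted p = 0.387 with an estimated correlation). EM6, a late embryogenesis protein gene, rose by 4.71, and PER1, a seed peroxiredoxin gene, was at least 5.65-fold higher, while M10 was at least 2.02-fold lower. Of the 23 listed seed genes 14 were kept, and members such as CRA1 and CRC passed the filter only through C3H17_OX, which favours a high median. The median was 0.77 with normexp and 0.62 without a filter, and 0.77 with probes above background on all 4 arrays, where the camera call was lost (adjusted p = 0.0513). The 12 measured regulators of seed maturation moved both ways, 2 up and 2 down, with a median of -0.06 (camera adjusted p = 0.901). FUS3 was at least 1.98-fold and ABI5 at least 2.61-fold higher, whereas LEC1 fell by 1.99 and AGL15 was also called lower.

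Of 34 abscisic acid and dehydration genes, 14 rose and 0 fell, with a median of 0.89 (camera adjusted p = 7.61e-08; adjusted p = 0.387 with an estimated correlation). Among those higher were the cold-regulated COR15B (2.68), the dehydration gene RD20 (2.46), the phosphatase gene HAI1 (2.35) and NCED3, an enzyme of abscisic acid synthesis (at least 5.70-fold). Of 24 salicylate and immunity genes, 8 rose and 0 fell, with a median of 0.67, or 0.59 with bounds (camera adjusted p = 2.40e-04; adjusted p = 0.387 with an estimated correlation), led by FMO1 (2.62), the glucanase gene PR2 (2.07), NIMIN1 (at least 4.88-fold) and ALD1 (at least 1.18-fold). Of 29 jasmonate and ethylene defence genes, 8 rose and 0 fell, with a median of 0.58 (camera adjusted p = 5.30e-06; adjusted p = 0.387 with an estimated correlation), among them the vegetative storage proteins VSP2 (3.11) and VSP1 (2.40), the thionin THI2.1 (at least 6.13-fold) and TAT3 (at least 6.93-fold).

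Flavonoid and anthocyanin genes were higher in 8 of 19 and lower in 0, with a median of 0.75 (camera adjusted p = 5.86e-05; adjusted p = 0.387 with an estimated correlation), and 0.35 with probes above background on all 4 arrays. The MYB regulators of anthocyanin synthesis PAP1 and PAP2 rose by 4.30 and 3.36, and the glycosyltransferase gene UF3GT was at least 4.26-fold and the acyltransferase gene 5MAT at least 2.30-fold higher. Among 11 senescence and starvation genes, 3 rose and 0 fell, with a median of 0.88 (camera adjusted p = 3.16e-04; adjusted p = 0.387 with an estimated correlation). These were DIN2 (4.70), SAG13 (at least 25.2-fold) and the asparagine synthetase gene ASN1 (2.49), with SGR1 at 0.92. The 33 photosynthesis genes had a median of 0.10 and no called member (camera adjusted p = 0.00305; adjusted p = 0.387 with an estimated correlation), with PORA at 0.64, LHCB4.2 at 0.50 and LHCB2.2 at 0.48, and the call was lost with quantile normalization (adjusted p = 0.197).

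Glucosinolate biosynthesis genes were lower as a group. Of 19, 11 fell and 0 rose, with a median of -1.04 (camera adjusted p = 9.58e-06; adjusted p = 0.387 with an estimated correlation), and CYP79F2, SOT18, BCAT4 and MAM3 fell by 1.48, 1.43, 1.40 and 1.40. The 27 cell cycle and DNA replication genes had a median of -0.56 (camera adjusted p = 5.86e-05; adjusted p = 0.387 with an estimated correlation), with 1 call, the mitotic cyclin CYCB1;1 (-1.36), and with PCNA1 at -0.98 and the cytokinesis syntaxin KN at -0.90. The 18 expansin and xyloglucan endotransglucosylase genes of cell wall expansion had a median of -0.54 (camera adjusted p = 0.0247; adjusted p = 0.456 with an estimated correlation), although XTH24 rose by 1.57 while XTH33 fell by 1.14. Markers of root tissue had a median of -0.42 over 20 genes (camera adjusted p = 0.00475; adjusted p = 0.571 with an estimated correlation; adjusted p = 0.0522 without a filter), and the root hair regulator RSL4 and PRP3 fell by 1.95 and 1.19.

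The remaining lists did not pass camera, although the medians of promoters and repressors of flowering lay at percentiles 99.45 and 1.38 of random lists. Promoters of flowering had a median of 0.30 over 21 genes (adjusted p = 0.212) and 0.02 with normexp, with 3 higher, the MADS-box genes FUL (1.52), CAL (at least 1.78-fold) and AP1 (at least 1.73-fold), and AGL17 lower (-1.16). Repressors of flowering had a median of -0.30 over 16 genes with no call (camera adjusted p = 0.284), where FLC was at -0.73, TFL1 at -0.71, MAF4 at -0.69 and CDF1 at 0.96. Floral organ genes had a median of -0.22 over 7 (camera adjusted p = 0.398) and SEP1 fell by 1.17. The 22 clock genes had a median of 0.01 (camera adjusted p = 0.672), with PRR3 called at -1.02 and LHY at 0.87, and the 17 auxin response genes a median of -0.09 (camera adjusted p = 0.212), with IAA5 called at -1.47. Gibberellin genes had a median of -0.13 over 20 with no call (camera adjusted p = 0.489) and GA2OX1 at -0.99. Heat shock genes had a median of 0.05 over 12 (camera adjusted p = 0.505), where BIP3, a chaperone gene of the endoplasmic reticulum, was at least 15.9-fold higher and HSP23.6-MITO at least 8.35-fold lower. The 11 reference genes had a median of -0.11 and no call (camera adjusted p = 0.672), from -0.60 for UBQ5 to 0.41 for UBQ10. In every list, the members called were equally many when adjusted over the list alone. All 11 list calls, 7 higher and 4 lower, rested on the preset correlation, which is an assumption, and none held with an estimated one. That second test had only 1 residual degree of freedom and could hardly call a list, so it does not judge the calls. Calls were lost where the estimated correlation lay below the preset 0.01, as for abscisic acid genes (-0.0267), and above it, as for root markers (0.116).

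**Figure D2:**
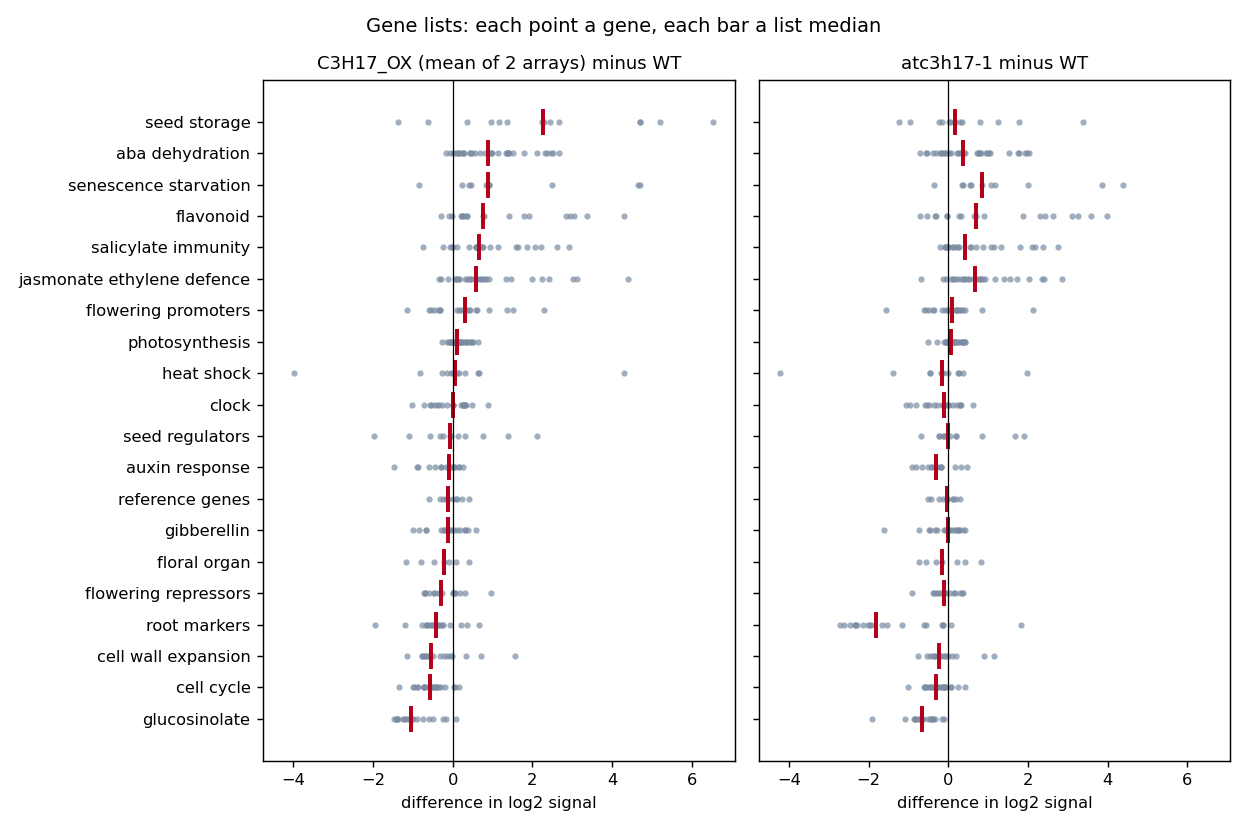
Each point is the difference in log2 signal from WT of 1 gene of a fixed list, for the mean of the 2 C3H17_OX arrays on the left and for atc3h17-1 on the right, and each bar is the list's median. The seed storage list has a median of 2.26 in C3H17_OX and 0.15 in atc3h17-1, and the root markers -0.42 and -1.81.

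The atc3h17-1 array was compared with WT to see what differs when C3H17 is mutated. Apart from AT2G02160 itself, PNP-A (54.1-fold), AT1G09500 (at least 51.9-fold) and ELI3-2 (at least 50.1-fold) were far above WT, as in C3H17_OX, and AT1G80133 (at least 13.2-fold), AT5G53780 (at least 10.8-fold), AT2G21480 (at least 10.7-fold), AT5G28237 (at least 8.95-fold) and AT1G05085 (at least 8.07-fold) were well above background in atc3h17-1 alone. The lowest, besides AT2G02160, were AT3G58480 (at least 9.93-fold) and the AP2/ERF gene PUCHI, known from lateral root primordia (at least 6.65-fold), then AT5G20440 (at least 9.75-fold), AT1G13510 (at least 7.93-fold), AT1G26890 (at least 6.52-fold), AT3G14160 (at least 6.02-fold) and AT1G52390 (at least 5.87-fold), which were detected on the WT array alone. The 5 genes detected in atc3h17-1 alone had 1 probe each, and 123 probes had such a pattern on that array. On the WT array 85 probes had it, and there 1 bright spot would put a gene below WT in both lines. AT3G58480 differed between the C3H17_OX arrays too, with an SE of 3.23. By size, 1757 genes were at least 2-fold different, 889 higher and 868 lower, or 815 and 424 with normexp. Unchanged groups simulated with noise resampled from the C3H17_OX array pair gave 137 higher and 137 lower. With that noise widened on the WT array, probably too far, they gave 404 and 405. A share of these genes may thus be noise of the WT array. With 1 array per line there was no replicate check and no p-value. The count was 899 with probes above background on all 4 arrays, and 122 of 227 genes with several probes had every probe past 2-fold. Of all 20462 genes 6058 had several probes, but of these 1757 only 227 did, so genes with 1 probe passed 2-fold more often.

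Root markers were the list furthest from WT in atc3h17-1, with 13 of 20 genes at least 2-fold lower and a median of -1.81, below all of 10000 random lists. PRP3 was at -2.72, the Casparian strip gene CASP1 at -2.47, the root hair expansin EXPA7 at -2.36 and CASP5 at least 3.62-fold lower. The list stands for root tissue in a whole seedling, so all list values of this line were measured beside that difference. Auxin response genes had a median of -0.32 (percentile 0.04), with LBD16 at -0.90 and IAA19 at -0.82. Glucosinolate genes had a median of -0.66 (percentile 0), with CYP79F2 at -1.10, cell cycle genes -0.30 (percentile 0), with CYCB1;1 at -1.02, and cell wall expansion genes -0.22 (percentile 1.03), a value that became -0.09 (percentile 12.7) once the position trend was removed.

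Above WT were senescence and starvation genes (median 0.85, 5 of 11 at least 2-fold higher), flavonoid genes (0.69, 8 of 19), jasmonate and ethylene defence genes (0.67, 8 of 29) and abscisic acid and dehydration genes (0.37, 8 of 34), each at percentile 100 of the random lists, and salicylate and immunity genes (0.41, 8 of 24) at percentile 99.98. DIN2 was at 4.39, PAP1 at 3.97, DFR at 3.26, the defensin gene PDF1.2A at 2.03 and RD29A at 2.03. Photosynthesis genes had a median of 0.06 (percentile 98.85), which turned to -0.0092 with quantile normalization. The salicylate median was 0.20 with probes above background on all 4 arrays and 0.23 with the brightest probe. The other lists lay nearer the middle of the random lists. These were seed storage (median 0.15, percentile 75.9, with EM6 at 3.37), seed regulators (-0.01, 53.1), flowering promoters (0.09, 88.0), flowering repressors (-0.10, 22.1), floral organ genes (-0.15, 32.7), clock (-0.12, 11.2), heat shock (-0.15, 20.2), gibberellin (0.00, 63.4) and reference genes (-0.03, 54.4).

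Both lines were next compared with each other through WT. PNP-A, ELI3-2, AT1G09500, GSTU11 (28.2-fold in atc3h17-1), PCC1 (23.2-fold) and LTP4 (at least 14.2-fold) were far above WT in both, so that overexpressor and mutant shared many of their highest genes. In all, 529 genes were at least 2-fold higher in both, against 38.8 expected for independent lists of these sizes, and 309 lower in both, against 24.1. Unchanged groups with a shared WT array gave 48.1 and 48.5 such genes on average over 100 simulations with noise resampled from the C3H17_OX array pair, and 287 and 290 with that noise widened 3.57 times on the WT array. With C3H17_OX read from 1 probe and atc3h17-1 from another probe of the same gene, 35 of 4190 genes were higher and 5 lower in both, against 1.72 and 0.196 for independent lists and 68 and 7 with both lines read from the same probe. Over 20462 genes the differences from WT correlated with r = 0.679 (Spearman's rho 0.724). Both differences share the single WT array, and unchanged groups simulated with the repeated-spot noise of each array gave r = 0.936. The covariance was 0.325 against 0.0306 in that simulation, a difference of 0.294, but 0.395 with the widened noise. Unchanged groups with the widened noise thus exceeded the observed covariance, so that noise was probably too large for these arrays. The size of a shared effect was not settled, since the WT noise over all genes was not measured. Over the 4190 genes the covariance was 0.154 from the same probe and 0.0940 from separate probes. Part of the excess may come from the shared WT array, a single array that could not be split.

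Genes past 2-fold in opposite directions numbered 11, most of them at background in at least 1 group. AT5G10040 was measured in all groups, at 1.31 in C3H17_OX and -1.27 in atc3h17-1, and C3H17 was described above. AT3G46410, AT2G29870 and the hypoxia-related ERF71 were well above background in C3H17_OX alone, so their direction in atc3h17-1 stays open, and AT5G04120 was not well above background in atc3h17-1. AT1G23690, the gamete fusion gene HAP2, AT4G28815, AT3G44070 and AT1G09157 were not well above background in C3H17_OX or WT, so no direction is given for C3H17_OX, and in atc3h17-1 they were at least 5.45-fold, 2.41-fold, 1.50-fold, 2.32-fold and 2.82-fold above WT. By size, 6 were higher in C3H17_OX and lower in atc3h17-1 and 5 the reverse, against 37.9 and 24.7 for independent lists and 0.53 and 0.50 in the simulation with widened noise. The independent value leaves out the shared WT array, which works against opposite moves, so the shortfall carries no meaning of its own, and with separate probes the counts were 1 and 1 against 0.563 and 0.597. The count was 2 with normexp, 1 with probes above background on all 4 arrays, and 23 without C3H17_OX array 1 or 28 without array 2, where 1 array past 2-fold was enough.

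**Figure D3:**
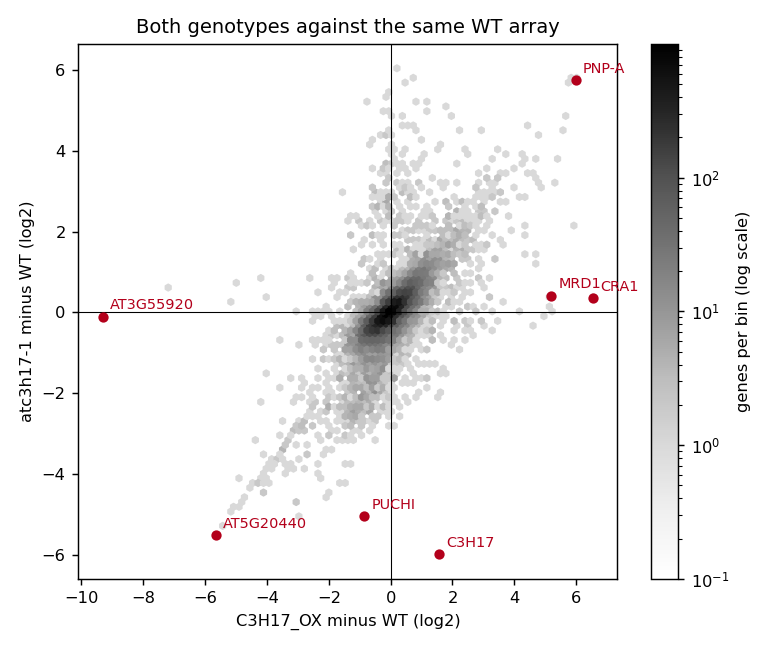
For each gene, the difference in log2 signal from WT is plotted for C3H17_OX (horizontal axis) against atc3h17-1 (vertical axis), with grey for the number of genes per bin on a log scale and 7 named genes in red. Most genes lie along the rising diagonal (r = 0.679), C3H17 lies low on the vertical axis, where 2 of its 3 probes were not well above background in atc3h17-1, and AT3G55920, at background in C3H17_OX, at -9.31 and -0.11.

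A further comparison set C3H17_OX against the mean of WT and atc3h17-1, which rests less on the single WT array but answers another question, since atc3h17-1 is not a wild type. CRA1 was at least 25.1-fold above WT and at least 24.1-fold above atc3h17-1, and CRC at least 12.2-fold and 11.7-fold. MRD1 was 36.5-fold above WT and 27.4-fold above atc3h17-1, and NUDT24 was at least 16.2-fold above WT and 13.1-fold above atc3h17-1, where it was measured. AT3G55920 (at least 145-fold and 134-fold), AT2G43280 (at least 47.5-fold and 72.8-fold) and AT3G05170 (at least 28.2-fold and 32.3-fold) were low against both. limma called 821 genes against the mean, 479 higher and 342 lower, or 251 and 94 with normexp. The count was 388 with probes above background on all 4 arrays and 18 with WT and atc3h17-1 pooled as 1 group, whose spread then holds their own difference.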

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

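The test in this part was chosen after the result was seen. Probes that matched no locus by transcript accession were outside the gene comparisons. Of 4653 such probes kept by the background filter, 236 were at least 2-fold higher than WT on both C3H17_OX arrays and 206 at least 2-fold lower. The group with the higher signal had to be well above background. Without that condition, 894 of 20462 genes were higher and 568 lower. In atc3h17-1, 395 of these probes were higher and 248 lower, against 889 and 868 genes. In both lines, which share the single WT array, 119 probes were higher, and no count for unchanged probes was simulated. No explanation was tested for these probes, which carry no gene name here.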

How the results depend on the processing

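Removal of the position trend, the other baselines and the requirement on every probe were chosen after seeing the data. No paired analysis was possible because only C3H17_OX carries replicate numbers. Every count and list total not given here stayed within 1.5 times its value or on its side of the threshold, and no scaling moved the median of all genes by more than 0.1. The cause of the changes below was not tested, except where a setting tests fewer or more features by construction. Signal over background limits most bounds, since many of the largest differences have a group at background.

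For C3H17 in C3H17_OX, the brightest probe and A_84_P221496 alone each gave -0.027, and leaving out 1 array gave 1.54 to 1.56; in atc3h17-1 the all-array filter gave 0.50. limma called 2434 probes in place of 1488 genes, 13586 genes with no fold threshold and 861 against atc3h17-1. Genes 2-fold apart on both C3H17_OX arrays numbered 940 with the all-array filter, 4054 at 1.5-fold, 570 at 3-fold, 912 against atc3h17-1, 259 against both other lines, 144 with every probe past 2-fold, and 1688 to 1690 without 1 array, where the other array alone had to pass. For atc3h17-1, they numbered 899, 3589 and 967 for the first 3 of these settings, 1047 against the C3H17_OX mean and 122 with every probe past 2-fold. Against the mean of WT and atc3h17-1, limma called 345 with normexp, 388 with the all-array filter, 18 with both pooled and 1389 probes.

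Of the 11 list calls, 0 held with an estimated correlation, a test with 1 residual degree of freedom that could hardly call any list. Against atc3h17-1, 5 lists passed, 4 of them in the same direction, while the root markers turned to 1.25. By percentile among random lists 13 lists lay outside, 8 higher and 5 lower, with promoters (99.45) and repressors (1.38) of flowering added to the 11. Seed storage was lost with the all-array filter, root markers without a filter and photosynthesis with quantile normalization (camera adjusted p = 0.0513, 0.0522 and 0.197), and auxin response was gained without the position trend (0.0220). In atc3h17-1 the photosynthesis median turned to -0.0092 with quantile normalization. The correlation of both differences was 0.787 with normexp, 0.686 with quantile normalization, 0.653 without a filter, 0.754 with the all-array filter, 0.683 with the brightest probe, 0.660 without the position trend and 0.665 to 0.670 without 1 array. Oppositely moved genes numbered 2 with normexp, 1 with the all-array filter, 23 without C3H17_OX array 1 and 28 without array 2, for which 1 array was enough. Without the position trend, 1200 of the 1462 genes of C3H17_OX and 1565 of the 1757 of atc3h17-1 kept their direction past 2-fold. Named genes were followed with normexp, quantile normalization, median scaling, the series value table, no filter, the all-array filter, the brightest probe and no position trend. The all-array filter dropped named genes at background, and genes with 1 probe cannot change with the brightest probe. In C3H17_OX, values of named genes other than C3H17 stayed on their side of the threshold 795 times and lost it 33 times, 22 of them with normexp. They gained it 15 times and reversed 0 times. In atc3h17-1, values of named genes stayed within the difference between the C3H17_OX arrays, as an SD, 514 times and moved beyond it 281 times, 100 of them with normexp and 70 without the position trend, and AT2G02160 reversed with the all-array filter.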

Other observations

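The tests in this part were chosen after the results were seen. Set against atc3h17-1 instead of WT, C3H17_OX kept seed and abscisic acid genes higher, with fitted list medians of 1.86 (camera adjusted p = 2.12e-04) and 0.41 (2.84e-07), and cell cycle and glucosinolate genes lower, at -0.36 (2.12e-04) and -0.33 (0.00359). Root markers were 1.25 higher in C3H17_OX than in atc3h17-1 (1.57e-04), and none of these 5 camera calls held with an estimated correlation (adjusted p = 0.667). Defence, flavonoid and senescence genes did not differ past the threshold between the lines, with medians of 0.16 for salicylate (0.228), 0.02 for jasmonate (0.494), 0.06 for flavonoids (0.556) and 0.08 for senescence (0.548).

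Genes apart from both other genotypes were counted by unlike rules. C3H17_OX had to pass 2-fold on each of its 2 arrays, but atc3h17-1 on its 1 array, against WT and the C3H17_OX mean. These genes numbered 165 higher and 94 lower in C3H17_OX, and 243 higher and 393 lower in atc3h17-1, counts that are not comparable. In C3H17_OX they included the seed genes CRA1, CRC and PER1, and BGLU19, a beta-glucosidase gene (at least 7.90-fold above WT and at least 7.57-fold above atc3h17-1), AT3G54800 (at least 7.06-fold and 6.76-fold) and AT5G35660 (log2 differences of 4.12 and 4.06), whereas CNGC12, a cyclic nucleotide-gated channel gene (-3.04 and -3.12), and HEC1, a bHLH gene (-2.28 and -2.78), were lower. In atc3h17-1 the arabinogalactan gene AGP30 (-4.53 relative to WT) and WAKL5, a wall-associated kinase-like gene (at least 1.49-fold below WT), were low against both.

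The line labelled as overexpressor and the line with a mutant allele of C3H17 differed from WT mostly in the same direction. Uneven signal on the WT array does not account for it alone, since 678 of 838 genes that moved together (80.9%) still did so without the position trend. That share lies just past the 80% set for this test, so part of the pattern may come from the uneven surface. Error of single WT spots would leave no covariance between different probes of a gene. Over the 4190 brighter genes with 2 probes well above background and a mean above -3, that covariance was 0.094, against 0.154 from the same probe. For all genes such error stays open. Unchanged groups with noise widened on the WT array gave 577 genes in the same direction of the 838 observed, but 96.6 without the widening. The widened noise was probably too large, since its covariance (0.395) exceeded the observed 0.325. A shift of several hours in sampling time would move the clock list, whose median absolute difference lay at percentile 64.0 of random lists in C3H17_OX and 89.2 in atc3h17-1. Those random lists came from the same arrays, where many genes differed from WT in both lines, so these percentiles do not exclude such a shift. It also stays open that the 1 WT sample may itself stand apart, for instance in stress or nutrition, which cannot be told apart from a response common to both lines with 1 WT array.

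Seed storage genes were higher in C3H17_OX, and the kept seed genes had a median of 2.28 without the position trend, against 2.26 with it. The uneven WT surface, with a trend of -0.33 to 0.32, was too small to account for that median, whatever its removal gave. The filter favoured the median by keeping members detected in C3H17_OX alone. Seed tissue in the sample stays open, since 13 of the 23 listed genes were well above background on both C3H17_OX arrays, against 6 on WT and 7 on atc3h17-1. The abundant seed transcripts CRB and SESA1 to SESA5 were among those not well above background, but these 6 were picked after their values were seen and whether their probes work was not checked. A peculiarity of the single sample also remains, as the difference between the C3H17_OX arrays did not carry over between probes (r = -0.0403). A response to C3H17 in this line may thus be one explanation among several.

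The neighbouring genes AT3G55910 (at least 11.3-fold below WT, with 0.73 in atc3h17-1) and AT3G55920 were at background in C3H17_OX alone. On both C3H17_OX arrays, 2 probes of the pair were at background and at least 8-fold lower. Independent failures would give 0.00414 such probes over the whole array, at the upper limit of the rates outside the pair. This comparison cannot argue against failed spots, since the pair was chosen by that pattern. Of other genes, 5 probes had the pattern on both arrays, and 0 probes had it on 1 C3H17_OX array alone. The 0 argue against spots that failed independently on each array, but failures common to both arrays were not tested. The pair was noticed among the lowest genes, so whether neighbours arise by chance was not tested. A loss or silencing of that stretch in the line is a candidate explanation that stays open, with a run of only 2 genes, AT3G55890 at 0.80 and AT3G55930 at 0.28 on either side. No genome sequence of the line was used here.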
